A study of Homo sapiens with 8 samples.

How the data were processed

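The series comprised chromatin immunoprecipitation sequencing of NCI-H69 cells with antibodies against RBBP4 and P300, after transfection with siRNA against CSNK2B or non-targeting siRNA. Per the labels, cells were fixed with 1% formaldehyde for 10 min, harvested 48 h after transfection, and sequenced as paired 150 bp reads. Each antibody and arm had 1 immunoprecipitated and 1 input library, 8 in all, and the labels gave 1 batch per antibody. Tools named in the submitters' processing notes were FastQC, Trim Galore 0.6.7, Bowtie2 2.4.5, MACS2 2.2.7.1, DiffBind 3.4.11 and ChIPseeker 1.28.3, with the build GRCh38, and the role of each was not given in the sources used here.

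The authors deposited 1 table of regions per antibody, with RPKM values for the knockdown and control immunoprecipitated libraries. The log2 fold change and the mean log2 CPM of each region are the authors' values, per the file headers. The p-value and its adjusted value are the authors' as well, per the file headers, and all deposited p-values lay below 0.05. Region names begin with the arm in which a peak was called, and that arm was the higher one for 20496 of 20496 P300 regions and 35151 of 35154 RBBP4 regions. The number of regions tested was worked out from the ratio of adjusted to unadjusted p-values as 95329 for RBBP4 and at least 134012 for P300. Knockdown and control columns were identified by name alone. No input column was used, and no column of another sample was present.

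RPKM multiplied by region width gave whole reads, within 0.01 of a read, for 99.4% of P300 and 98.3% of RBBP4 regions. For the other 132 P300 and 596 RBBP4 regions a width was solved that made both libraries whole and returned the deposited log2 fold change. The total by which the deposited RPKM was scaled was taken to be the reads in all tested regions, which was not checked. The authors' log2 fold change was scaled to whole libraries. The shift between these scalings was 0.44 (log2) for P300 and -0.58 for RBBP4. Whole-library sizes, in units of 1e6 reads as estimated from the deposited log2 values, were 22.5 and 19.1 for P300 knockdown and control, and 19.1 and 19.7 for RBBP4. The tested regions held 4.20%, 5.71%, 6.33% and 4.23% of these, in the same order. Listed regions had a median of 3, 8, 14 and 6 reads per library.

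The main measure was log2 of the knockdown over the control RPKM with a pseudocount of 1, which understates ratios of low regions, and regions with an absolute value of at least 1 were counted per direction. In the text a listed region is called higher or lower by the sign of the authors' log2 fold change. Folds of named regions were computed from recovered reads scaled to all tested regions, with a floor of 3 reads per library in place of 0. A bound from that floor takes the reads of the other library as fixed and lies above the lower limit of the exact interval, which was 9.20 for CTTNBP2NL. With 1 library per arm no test of the conditions was possible. The RBBP4 p-values were matched by a beta-binomial tail with a dispersion of 0.01, and adjusted calls were recomputed from recovered reads with dispersions of 0.04 and 0.16.

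Gene positions came from RefSeq genes of GRCh38.p14, the build of the tables, without strand or exons. The planned promoter, exon and intron classes were therefore replaced by distance to either end of a protein-coding gene (3000 bp, or 1000 bp as an alternative) and by gene spans. Shares were compared with 100 circular shifts of all regions of a chromosome, which can place regions in unassembled sequence. Genes were assigned regions within their span or 3000 bp of it. The 22 gene lists, with 451 members that all matched a gene symbol, were fixed before the data were examined. Members shared between lists were FOXA2 and NKX2-1 (neuroendocrine, MYC family and lineage), GAPDH and PGK1 (glycolysis, housekeeping) and B2M (antigen presentation, housekeeping). List medians of at least 3 members were ranked among 10000 random lists matched on level. The count of members with a called region at a gene end, ranked among lists matched on gene length, was added after the data were examined.

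Named genes followed a rule fixed beforehand: per antibody and direction the 10 genes with the largest absolute log2 ratio at or above the median level, up to 4 members per list by the same ranking, and 14 genes named in advance, not all of which are reported here, run over the listed regions only. Examples in the text were taken from these, and the regions with the smallest p-values were added after their values were seen. On simulated reads for the real regions, 99.97% of 20496 P300 and 99.9% of 35154 RBBP4 regions returned their reads. Planted lists with a log2 shift of 1.5 were found in 98% of P300 and 94% of RBBP4 trials, with 3% and 4% of unshifted lists found. These trials used ratios drawn from a normal distribution and lists made only of genes with a region. The planted lists were larger than any P300 list, of which the largest had 16 members with a region. The rates therefore do not carry over to the P300 lists. Random placements of 3000 regions fell within the shifted range in 90% and 85% of trials. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives covered the pseudocount, fold threshold, level and width filters, centring, scaling, adjusted p, window, overlap and the region taken per gene.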

Results

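NCI-H69, an established human small cell lung cancer line, was transfected with small interfering RNA against CSNK2B, the gene of the regulatory beta subunit of casein kinase 2, or with non-targeting RNA, and chromatin was taken 48 h later. Chromatin bound by RBBP4, a histone-binding protein shared by several deacetylase, Polycomb and chromatin assembly complexes, and by P300, the acetyltransferase encoded by EP300, was sequenced as paired 150 bp reads. The series held 8 libraries, with 1 immunoprecipitated library and 1 input library per antibody and arm, so no difference had a replicate check. The libraries of each antibody carried their own batch label, and folds were taken only within an antibody, so any difference between the antibodies is confounded with batch. The input libraries were not used here. Reads in all tested regions were not counted but inferred from the scaling of the deposited RPKM, without a check. They came to 946392 in the P300 knockdown library, 1092789 in the P300 control library, 1207945 in the RBBP4 knockdown library and 833181 in the RBBP4 control library. Each table listed only regions whose p-value in the authors' deposited table lay below 0.05, so a gene without a listed region was not shown to lack a change. Per the region names, the arm in which a peak was called was the higher one for 35151 of 35154 RBBP4 and 20496 of 20496 P300 regions. Counts per direction therefore nearly restate the arm of the peak call. Folds and p-values compare arms at regions chosen on 1 of them, which favours a difference in its direction. Column and region names, not a stated key, gave the arms. Columns named for the sample were read as knockdown and those named for the control as non-targeting. For RBBP4 the column names held only the initials of these words. A swap would turn every direction given here. Folds are ratios of reads scaled to all tested regions, with 95% exact binomial intervals that cover counting error only, and every count of 0 reads was replaced by a floor of 3 reads in that library. A fold given as at least a value rests on that floor and lies above the lower limit of its exact interval. Neither table listed a region at CSNK2B, and these data did not measure the knockdown itself.

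The first comparison asked where RBBP4 occupancy differed after CSNK2B knockdown. RBBP4 read density was higher after knockdown in 24180 listed regions and lower in 10974. Higher regions lay at gene ends more often than shifted placements did, among them ends of cell cycle, redox, glycolysis, ribosomal protein and housekeeping genes, and lower regions less often. At MYC, the proto-oncogene transcription factor, the region at chromosome 8, 127733928 to 127738714 (GRCh38), held 1433 reads after knockdown against 411 in the control, a 2.405-fold higher density (2.15 to 2.69). It lies in a chromosome 8 segment, described below, where read density was raised in both RBBP4 libraries. There 188 of 198 listed regions were higher, with a median log2 ratio of 1.04, so the MYC difference was not particular to that gene. At CDC6, a DNA replication licensing gene, the counts were 122 and 13, a 6.47-fold higher density (3.65 to 12.5). An adjusted p below 0.05 in the authors' deposited table was given to 16989 higher and 3142 lower regions, of 95329 tested.

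Listed RBBP4 regions held a median of 24 reads over both libraries where density was higher and 13 where it was lower. Of the 918 listed regions with at least 100 reads, 916 were higher. By the RPKM ratio, 22820 regions were at least 2-fold higher and 10974 at least 2-fold lower, a share of 67.5% higher. That share was 49.6% at 4-fold and 89.8% among regions with at least 20 reads. The deposited p-values corresponded to a fixed dispersion of 0.01 and compared these libraries, not the conditions. With a dispersion of 0.04, 11638 higher and 827 lower regions passed an adjusted p of 0.05 (68.5% and 26.3% of the authors' calls kept). With 0.16 none did, but there the p of a 4-fold difference is at least 0.0205 at any depth.

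Higher RBBP4 regions were concentrated at gene ends. Within 3000 bp of an end of a protein-coding gene lay 30.4% of higher regions (29.8 to 31.0), against a mean of 7.70% and a maximum of 8.44% over 100 placements shifted along each chromosome. Among lower regions the share was 4.79% (4.40 to 5.21), under the lowest shifted share of 6.10%. Gene spans held 58.0% of the higher regions, against a shifted mean of 43.2%. Shifted placements are not RBBP4 peaks, and tested regions that were not listed could not serve as a reference. These shares therefore do not separate where RBBP4 peaks lie from where they changed. Lower regions were also shallower, with a median of 13 reads against 24. The annotation used here gave no strand or exons, so promoters, untranslated regions and the far ends of genes were not separated. Counted by gene, 5961 of 20037 protein-coding genes (29.7%) had a higher region with an adjusted p below 0.05 in the authors' deposited table within 3000 bp of an end, and 182 (0.908%) had a lower one.

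**Figure D1:**
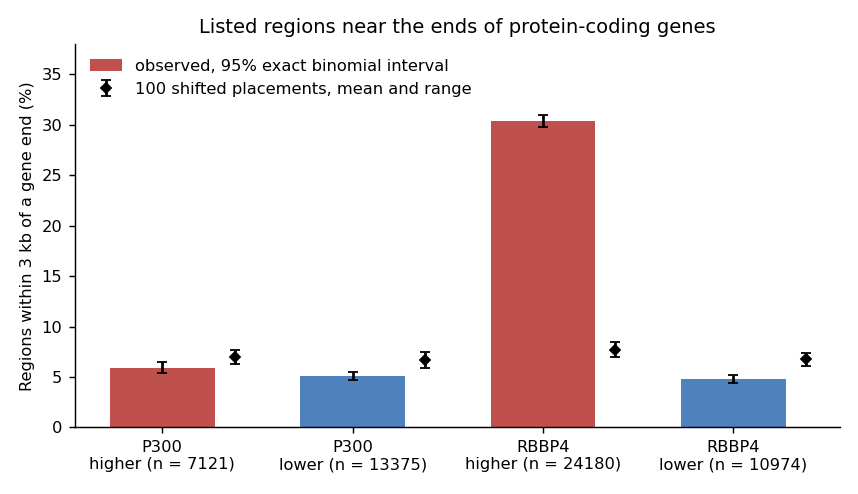
Share of listed regions within 3 kb of an end of a protein-coding gene (%), for regions with higher (red) or lower (blue) density after CSNK2B knockdown; bars show the observed share with its 95% exact binomial interval and diamonds the mean and range of 100 shifted placements. The RBBP4 higher regions reached 30.4%, above every shifted placement, while the other 3 sets lay between 4.79% and 5.93%.

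Gene groups differed in how many members carried such a higher RBBP4 region at an end. The count per list, compared with 10000 random lists matched on gene length, was chosen after the data were examined and describes these libraries. Of 22 lists, 9 lay at or above percentile 97.5 and 2 at or below percentile 2.5, where chance gives about 1 in all. The random lists were not matched on whether a gene had an RBBP4 peak at an end. Peaks without a listed change were not available, so having a peak was not separated from a change at it. Among E2F and cell cycle genes 21 of 30 had a higher region (percentile 100), including PLK1, a mitotic kinase, with 54 reads against 5 (7.45-fold, 3.003 to 23.9), RRM1, a ribonucleotide reductase subunit, with 28 against 2 (9.66-fold, 2.44 to 83.7), and BUB1, a spindle checkpoint kinase, with 50 against 6 (5.75-fold, 2.46 to 16.4). Iron, redox and ferroptosis genes had 11 of 15 (percentile 99.97). Examples were SLC7A11, the cystine transporter, with 35 reads against 2 (12.1-fold, 3.10 to 104), NQO1, a quinone reductase, with 33 against 2 (11.4-fold, 2.91 to 97.9), and KEAP1, the NRF2 inhibitor, with 84 against 14 (4.14-fold, 2.34 to 7.89). A region inside GCLM had the opposite direction, with 1 read against 12.

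Genes of complexes that contain RBBP4 carried a higher end region in 17 of 27 members (percentile 99.9). At RBBP4 itself the counts were 23 and 1 (15.9-fold, 2.58 to 654). Regions inside SIN3A and GATAD2A, both away from gene ends, had 2 reads against 14 and 2 against 13. Glycolysis genes had 13 of 20 (percentile 99.9), with PGAM1 at 41 reads against 7 (4.04-fold, 1.80 to 10.7), yet their median log2 ratio over regions near gene ends was low for their level (1.46, percentile 1.62 of random lists). PI3K, NF-kB and Wnt pathway genes had 15 of 24 (percentile 99.9), among them NFKB2 at 66 against 10 (4.55-fold, 2.33 to 9.93) and NFKBIA, an inhibitor of NF-kB, at 45 against 5 (6.21-fold, 2.47 to 20.04). Apoptosis and p53 genes had 11 of 20 (percentile 98.4). The region beside MCL1, an anti-apoptotic gene, had 16 reads against 0, at least 3.68-fold higher, and BBC3, a pro-apoptotic gene, had 50 against 5 (6.90-fold, 2.77 to 22.2) at a region 4853 bp from an end. Ribosomal protein genes had 17 of 34 (percentile 99.8), with RPS14 at 42 against 3 (9.66-fold, 3.09 to 48.7), and housekeeping genes 14 of 24 (percentile 99.8), with SNRPD3 at 51 against 3 (11.7-fold, 3.79 to 58.7). By the median log2 ratio of all regions at a gene, set as the test before the data were examined, only ribosomal protein genes (2.21, percentile 98.5) lay outside percentiles 2.5 to 97.5 of random lists of like level. Chance gives about 1 such list. The ribosomal call was lost with regions near a gene end (percentile 94.96), the region nearest an end (93.1) or the region of highest level (94.7).

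DNA repair genes had 18 of 34 with a higher end region (percentile 99.3). MRE11, a nuclease of double-strand break repair, had 1 read against 11 inside the gene, and BRIP1, a helicase, had 42 against 2 inside the gene (14.5-fold, 3.77 to 123). Histone acetyltransferase genes had 5 of 9 (percentile 92.8), with KAT5 at 34 against 1 (23.5-fold, 3.93 to 953), KAT7 at 42 against 4 (7.24-fold, 2.63 to 27.8) and EP300 at 30 against 6 (3.45-fold, 1.41 to 10.1). None of the 4 regions at CREBBP, the paralogue of EP300, had an adjusted p below 0.05 in the authors' deposited table. Of the casein kinase 2 genes, 0 of 4 had a higher end region (percentile 13.4), and a region inside CSNK2A1 had 10 reads against 2, with an adjusted p of 0.121 in the authors' deposited table. In the opposite direction, 1 other member was lower, with a log2 ratio of -3.14 near a gene end, also without an adjusted p below 0.05 there.

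Genes that mark the neuroendocrine identity of small cell lung cancer had 8 of 34 members with a higher end region (percentile 23.2). SEZ6, a neuronal surface protein, was among them, with 60 reads against 5 (8.28-fold, 3.36 to 26.4). In 3 members, RTN1 with 3 reads against 16 among them, a region in the gene or its flanks was lower with an adjusted p below 0.05 in the authors' deposited table. NEUROD1 and INSM1, transcription factors of that identity, and MYCL had no listed RBBP4 region. Non-neuroendocrine genes had 15 of 34 (percentile 96.5). NOTCH2 had 45 reads against 1 at a region inside the gene (31.0-fold, 5.29 to 1253), and ANXA1 had 21 against 1 (14.5-fold, 2.33 to 599). Lower regions by the same criterion lay at 4 members, including WWTR1 with 1 read against 12 and RAB27B with 2 against 13. Fibroblast genes, included as markers of another cell type, had 7 of 12 (percentile 96.3), including COL1A1 at 50 against 7 (4.93-fold, 2.22 to 12.9). T cell genes had 0 of 12 (percentile 0.495), innate sensing and interferon genes 1 of 18 (percentile 0.905), antigen presentation genes 2 of 14 (percentile 10.6), hepatocyte genes 2 of 14 (percentile 12.2), skeletal muscle genes 1 of 12 (percentile 6.94) and tuft cell genes 2 of 9 (percentile 31.5). Developmental Polycomb target genes had 12 of 35 (percentile 79.5), with HOXB13 at 67 against 9 beside the gene (5.13-fold, 2.55 to 11.7). MYC family and lineage oncogenes had 6 of 16 (percentile 76.4), with MYCN at 20 against 2 (6.90-fold, 1.68 to 60.9).

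**Figure D2:**
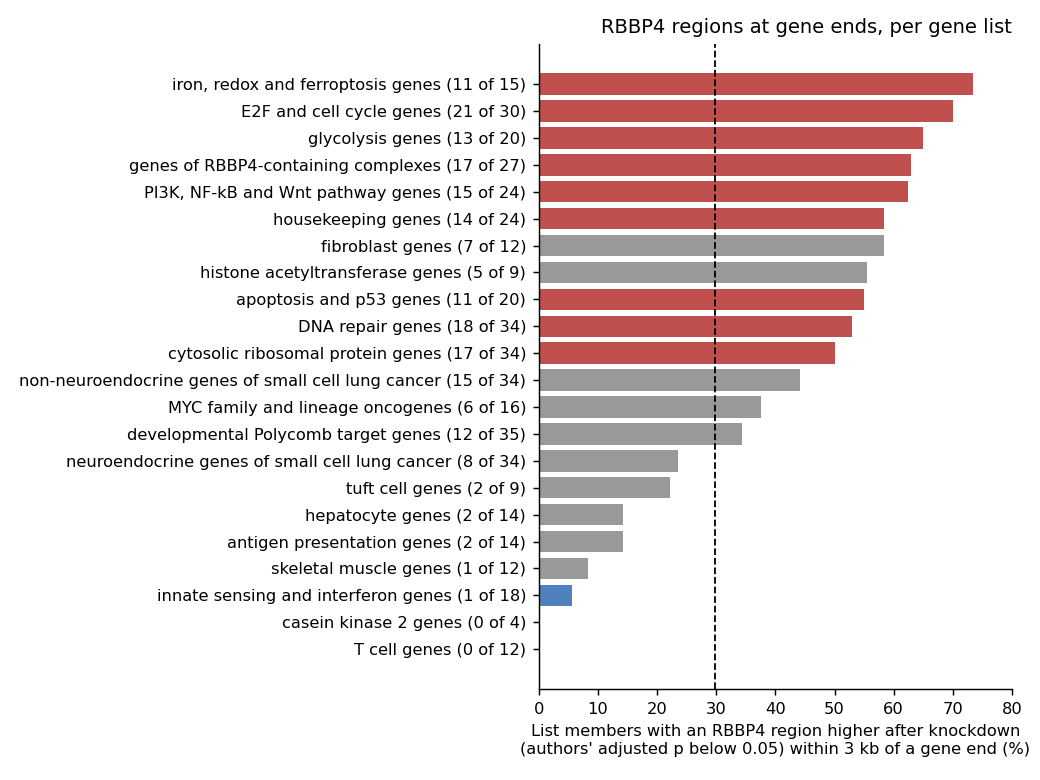
Percent of members of each gene list with an RBBP4 region that was higher after knockdown (adjusted p below 0.05 in the authors' deposited table) within 3 kb of a gene end; counts stand beside the list names and the dashed line marks all protein-coding genes (29.7%). Red bars lay at or above percentile 97.5 of length-matched random lists, blue at or below percentile 2.5 and grey between; T cell genes (percentile 0.495) and casein kinase 2 genes had 0 members and so no visible bar.

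The largest RBBP4 ratios above the median level were at regions without reads in 1 library. CTTNBP2NL had 51 reads after knockdown and 0 in the control, at least 11.7-fold higher. SYCE2 had 38 against 0 (at least 8.74-fold), ZMYM6 32 against 0 (at least 7.36-fold), PIK3R2 30 against 0 (at least 6.90-fold) and C8orf34 25 against 0 (at least 5.75-fold). SIK3, PTPRG, BTAF1, MRPS33 and KIZ had between 19 and 23 reads against 0. In the other direction ERMP1 had 0 reads against 16, at least 7.73-fold lower. SLC24A2 and HECW2 had 0 against 13 (at least 6.28-fold lower), and ANKRD62, CCNY, RFTN1, PLCB4, GMDS, GNA12 and GABBR2 had 0 against 12 (at least 5.80-fold lower). All 10 of these lower regions lay at least 2088 bp from the ends of their genes.

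The smallest adjusted p-values in the authors' deposited table belonged to deeply covered regions, chosen here after their values were seen. TRPS1, a GATA-type repressor, had 1344 reads against 185 inside the gene (5.01-fold, 4.29 to 5.88), with an adjusted p of 1.40e-28 in the authors' deposited table. COL14A1 had 830 against 119, SAMD12 1280 against 227, FBXO32 805 against 129, DERL1 663 against 113 and EXT1 807 against 146. All of these and MYC lay on chromosome 8 between 113 and 128 Mb, where read density was raised in both RBBP4 libraries over most 1 Mb bins. In that segment, which was chosen from these same values, the library with fewer reads had a median of 71.8 reads per kb over 198 regions, against 6.62 per kb elsewhere. The bin starting at 116 Mb was an exception, with a median of 8.02 per kb over 13 regions. In the P300 table the medians were 6.82 per kb over 149 regions of the segment and 5.92 per kb elsewhere, so the RBBP4 and P300 libraries differed there, and only their labels give both as NCI-H69. Around MYCN, a locus known to be amplified in NCI-H69, the medians were 4.64 per kb for RBBP4 and 5.76 per kb for P300. Neither was raised over the 6.62 and 5.92 per kb elsewhere. Outside the segment TLE4, a corepressor, had 276 reads against 23 (8.28-fold, 5.40 to 13.3), UNC5B 228 against 18, ZNF521 225 against 22, COLEC12 213 against 20, MLLT3 185 against 13 and SBF2 169 against 11.

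**Figure D3:**
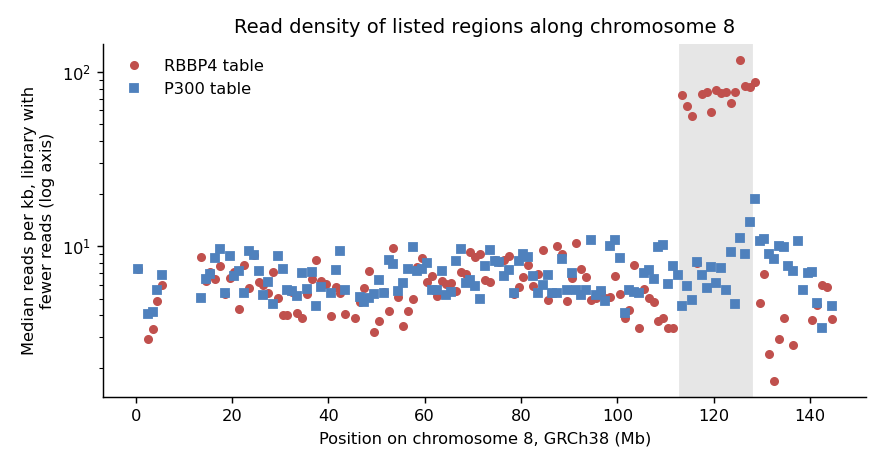
Median reads per kb (log axis) of listed regions in 1 Mb bins along chromosome 8 (GRCh38, Mb), taken per region from whichever library had fewer reads, for bins with at least 2 regions; circles are the RBBP4 table, squares the P300 table, and the grey band spans 113 to 128 Mb. RBBP4 medians in the band were mostly near the segment's 71.8 reads per kb, except 8.02 in the bin starting at 116 Mb, while P300 bins there stayed near the 6.82 reads per kb of that table's segment.

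The next comparison asked where P300 occupancy differed. P300 read density was higher after knockdown in 7121 listed regions and lower in 13375. At or above the median level 6104 regions were at least 2-fold higher and 4023 lower, but level went with direction among listed regions, since 85.7% of higher and 31.0% of lower ones lay there. With at least 20 reads the counts were 470 and 758. Regions were shallow, with a median of 12 reads over both libraries and a maximum of 59. In the authors' deposited table the lowest adjusted p was 0.260, so 0 regions passed 0.05, while all 20496 listed regions of at least 134012 tested had an unadjusted p below 0.05. DNA repair genes included members in both directions, and MYC, MYCN, EP300 and the neuroendocrine factors NEUROD1 and INSM1 had no listed P300 region.

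Within 3000 bp of a gene end lay 5.93% of higher P300 regions (5.39 to 6.50) and 5.11% of lower ones (4.74 to 5.49), against shifted means of 6.95% and 6.67% and lowest shifted shares of 6.29% and 5.94%. Within 1000 bp the share of higher regions, 3.06%, lay between its shifted mean of 2.71% and maximum of 3.15%. The largest ratios above the median level included LARP7, with 14 reads after knockdown against 0 at a gene end (at least 5.39-fold higher), PACS1 with 15 against 0 (at least 5.77-fold), VTI1B and CLASP2 with 13 against 0 (at least 5.00-fold), and DNAH9, MXRA7, SMG1, ASB4, ETV1 and CUL2 with 12 against 0 (at least 4.62-fold). Lower were ZNF16 with 0 against 13 (at least 3.75-fold lower), CCDC91 and a separate region of DNAH9 with 0 against 12 (at least 3.46-fold), ADAM12, SYT14 and IARS2 with 0 against 11 (at least 3.18-fold), and FCHO2, GPR158, LRRC4C and PLCB1 with 0 against 10 (at least 2.89-fold). The lower limits of the exact intervals were smaller than these floor values, such as 3.83 for LARP7 and 1.94 for FCHO2. MRE11 had regions with 1 read against 9 and 2 against 9.

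No P300 list median lay outside percentiles 2.5 to 97.5 of random lists. Of 16 DNA repair genes with a listed P300 region, 5 were at least 2-fold higher and 11 at least 2-fold lower by mean log2 ratio (percentile 26.0). XRCC1 had 11 reads against 0 (at least 4.23-fold higher) beside the gene and NBN had 11 against 1 (12.7-fold, 1.85 to 547). Neuroendocrine genes had 1 higher and 6 lower of 8 (percentile 22.5), with SCG3 at 17 against 3 and RTN1 at 1 against 10. Non-neuroendocrine genes had 3 higher and 3 lower of 7 (percentile 27.4), with ABCC3 at 32 against 10 (3.70-fold, 1.77 to 8.43) and AXL at 26 against 9 (3.34-fold, 1.51 to 8.09). PI3K, NF-kB and Wnt genes had 2 higher and 6 lower of 8 (percentile 12.04), with RPTOR at 1 against 12, and genes of RBBP4-containing complexes 1 higher and 4 lower of 6 (percentile 4.65, or 2.27 with the region nearest a gene end), with MTA3 at 2 against 11, LIN52 at 2 against 9 and, higher, EZH2 at 13 against 3. E2F and cell cycle genes had 1 higher and 3 lower of 4 (percentile 15.4), apoptosis and p53 genes 1 and 3 of 4 (percentile 12.1), Polycomb targets 2 and 2 of 4 (percentile 59.8), ribosomal protein genes 1 and 1 of 3 (percentile 23.1), tuft cell genes 2 and 1 of 3 (percentile 95.7), T cell genes 2 and 1 of 3 (percentile 92.2) and fibroblast genes 1 and 2 of 3 (percentile 45.0). Acetyltransferase, MYC family, glycolysis, housekeeping, hepatocyte and muscle lists had 1 or 2 members each, and casein kinase 2, antigen presentation, innate sensing and iron and redox lists had 0.

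The final comparison asked whether the antibodies shared regions. P300 and RBBP4 regions overlapped by at least 1 bp in 317 pairs, against a mean of 203.84 and a maximum of 256 over 100 shifted placements. Both were higher in 101 pairs (shifted range 35 to 66) and both lower in 59 (23 to 54). P300 was lower and RBBP4 higher in 125 pairs (67 to 123), and P300 higher and RBBP4 lower in 32 (7 to 28). Directions matched in 50.5% of pairs, where independent directions with the same splits give 46.6%. Across these regions, which are not independent replicates, the log2 ratios had a Pearson r of 0.082 and a Spearman rho of 0.058. By gene, 1535 genes had a higher region in both tables where independent lists would share 1072, and 1376 had a lower region in both where 524 would be shared, without control for gene length.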

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

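The tests of the chromosome 8 segment and of immunoprecipitation efficiency were chosen after the results were seen, and those of dispersion and scaling were added after the data were seen but before their own results were, except that the depth limit of the dispersion test and the limit from unlisted regions were worked out afterwards.

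Of listed regions, 68.8% were higher for RBBP4 and 34.7% for P300, so the larger directions were opposite. The estimated share of each library in tested regions differed in the same directions. It was 6.33% after knockdown and 4.23% in the control for RBBP4, and 4.20% and 5.71% for P300. Whether such a difference in enrichment between libraries gives the opposition was not tested. At 4-fold the shares were 49.6% and 49.7%, but that threshold went with direction, so it cannot decide whether the opposition holds. It kept 10494 of 10974 RBBP4 lower and 6972 of 7121 P300 higher regions. Of the larger groups it kept 10344 of 22820 RBBP4 higher and 7060 of 13174 P300 lower regions. At or above the median level, which also went with direction, both were mostly higher (73.0% and 60.3%). With at least 20 reads the shares were 89.8% and 38.3%, and with the width filter 67.2% and 30.9%. The read filter went with direction for RBBP4, where it kept 13674 of 22820 higher but 1554 of 10974 lower regions. The width filter did so for P300, where it kept 4297 of 7121 higher and 9589 of 13174 lower regions. Of the P300 regions 0 passed an adjusted p of 0.05 in the authors' deposited table. The difference was not tested, since each arm was 1 library and each antibody its own batch.

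The excess of higher RBBP4 calls has several candidate explanations. Direction also followed the arm in which the peak was called in 35151 of 35154 listed regions, which none of the checks below removes. Scaling by reads in regions in place of whole libraries, a shift of -0.58 (log2), left 93.0% of the 16989 higher calls with a counting interval that excluded equality. That interval was not adjusted and included no dispersion, and the calls had already been selected for a difference, so a high share was likely. Calls were not made anew at the same threshold, so scaling stays open as their source. Their excess over lower calls stays open too, because the 60175 unlisted regions may hold lower ones that the bound set beforehand did not consider. A more efficient immunoprecipitation in the knockdown library may account for the excess, as 99.8% of the listed regions with at least 100 reads were higher (99.2 to 99.97, counting error only). Outside the chromosome 8 segment 753 of 753 were. Unlisted regions of that depth were not seen. A gain in occupancy predicts the same, and a gain equal at all regions would amount to the shift above. The excess was there with a dispersion of 0.04 (11638 higher, 827 lower), so a dispersion of that size would not remove it. The true dispersion cannot be estimated from single libraries. Larger ones stay open, because 0% of the higher calls passed with 0.16, where the p of a 4-fold difference is at least 0.0205 and the test could hardly have come out otherwise. Altered RBBP4 occupancy after CSNK2B knockdown, the explanation the design names, cannot be told apart from a difference between 2 single libraries.

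A signal outside the planned comparisons lay on chromosome 8 between 113 and 128 Mb, where the RBBP4 library with fewer reads had 10.8 times the median reads per kb of regions elsewhere (10.1 to 11.5 by resampling regions). The segment was set from these same values, as the span between the outermost 1 Mb bins with a median above 5 times the table median. A high ratio was thus fixed in part by that choice. Its interval covers neither the choice nor the likeness of neighbouring regions. The ratio at like fold and the 10th percentile given next use the same values, though the choice acted on bin medians only. Selection of deep regions by the p-value threshold argues for part of the raised density at most, since among regions of like fold the ratio was 5.35 (5.03 to 5.81). A copy gain in the cells of all 4 immunoprecipitated libraries is opposed by the P300 table, where the ratio was 1.15 (0.919 to 1.35), and strong occupancy at only some sites is opposed by a 10th percentile of 37.0 reads per kb inside, above the 90th percentile elsewhere of 13.4. A copy gain in the cells behind the RBBP4 libraries alone, which carry their own batch label and could differ from the P300 cells in line or passage, and broad RBBP4 occupancy remain as untested hypotheses, and the input libraries were not used here. Either would have to leave out the bin starting at 116 Mb (8.02 reads per kb) and take in the bin starting at 128 Mb (87.7 over 2 regions), and the MYCN locus, which is known to be amplified in NCI-H69, was raised in neither table (4.64 for RBBP4, 5.76 for P300).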

How the results depend on the processing

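The alternatives of scaling, adjusted p below 0.05, depth, dispersion and segment were chosen after seeing the data. No paired analysis was possible because each group held 1 library. Ratios over input were not run, and distances to gene ends replaced those to transcription start sites. Counts are regions at least 2-fold higher and lower unless stated, and the cause was not tested where no construction gives it. For P300 (7121 higher, 13174 lower) the lower count was 7060 at 4-fold (49.7% higher), 4023 at or above the median level (60.3%) and 3558 after centring (66.7%). The higher count was 4297 with the width filter. Both counts were 470 and 758 with at least 20 reads, and 0 and 0 at adjusted p-values below 0.05 or 0.001 in the authors' deposited table. For RBBP4 (22820 higher, 10974 lower) the higher count was 10344 at 4-fold (49.6% higher) and 5292 after centring (32.5%). Counts were 12060 and 4451 at or above the median level (73.0%), 13674 and 1554 with at least 20 reads (89.8%), and 6252 and 11 at an adjusted p below 0.001 (99.8%). At an adjusted p below 0.05 the lower count was 3142 (84.1% higher). Adjusted calls fell from 3142 to 827 lower regions with a dispersion of 0.04, and to 0 higher and 0 lower with 0.16. Within 1000 bp of a gene end lay 3.06% of higher and 2.33% of lower P300 regions, and 24.6% of higher and 1.68% of lower RBBP4 regions. Shared pairs numbered 60 with reciprocal overlap of 50%, 116 at or above both median levels, and 3429 as shared genes. Lists outside percentiles 2.5 to 97.5 of random lists numbered 1 for P300 with the region nearest a gene end (RBBP4-containing complexes, low), against 0. For RBBP4, against 1 (ribosomal, high), they numbered 2 with regions near gene ends (tuft cell and glycolysis, low), 0 with the nearest region and 1 with the region of highest level (housekeeping, high). The other 41 alternative values of these results stayed within 1.5 times the main count. The larger direction turned at the median level for P300, where level went with direction, and at 4-fold for RBBP4. The 4-fold threshold went with direction too, since 10494 of 10974 lower RBBP4 regions passed it but only 10344 of 22820 higher ones. The larger direction also turned after centring for both, which shows nothing about stability, since each table median (P300 -1.70, RBBP4 1.49) lay within the larger group by construction. List medians changed sign in 10 of 88 P300 and 4 of 105 RBBP4 alternatives, none for the ribosomal list, but for tuft cell genes near gene ends (RBBP4, -0.84). Without the chromosome 8 segment 22714 RBBP4 regions were higher and 10964 lower. P300 regions had a median of 12 reads, which leaves wide intervals.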

Other observations

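All correlations here were added after the data were examined, and the test outside genes was set before its result was seen while the test between tables and the bootstrap intervals were set after.

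The share of higher regions differed between chromosomes along with gene density. Across 23 chromosomes, the RBBP4 share rose with protein-coding genes per Mb (Pearson r 0.82, permutation p 2e-05, adjusted 0.0001 over 5 relations; Spearman rho 0.68, permutation p 0.00047, adjusted 0.00235), with r 0.62 without chromosomes 19 and 17. The P300 share did likewise (r 0.62, permutation p 0.00024, adjusted 0.000483; rho 0.65, permutation p 0.0011, adjusted 0.00275), with r 0.52 without the same chromosomes. Chromosomes are not replicates, and each arm was 1 library.

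Reads gained at genes could underlie the RBBP4 relation. Outside genes and their flanks r was 0.56 (bootstrap interval 0.137 to 0.785, permutation p 0.00521, adjusted 0.00651; rho 0.41, permutation p 0.0557, adjusted 0.0696), and 0.36 without chromosomes 19 and 17, so it rests in part on those. The value lay past the bound of 0.5 set beforehand against that explanation, but by less than its spread, so the explanation stays open. For P300 the value outside genes was as large as over all regions, r 0.63 (bootstrap interval 0.268 to 0.815, permutation p 0.00029, adjusted 0.000483; rho 0.53, permutation p 0.0106, adjusted 0.0176), and 0.42 without the same chromosomes. A bias shared by both knockdown libraries, such as base composition, may also contribute: the shares of both tables had r 0.42 (bootstrap interval -0.107 to 0.724, permutation p 0.0417, adjusted 0.0417; rho 0.32, permutation p 0.136, adjusted 0.136), and 0.37 without chromosomes 13 and 4, which decides neither way.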
